A study of Arabidopsis thaliana with 12 samples.

How the data were processed

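Total RNA from transformed root protoplasts was labelled with biotin and hybridised to 12 Affymetrix Arabidopsis arrays of 22810 probe sets, 3 for each combination of DEX and CHX, per the labels. The labels say that DEX moves the transcription factor into the nucleus and that CHX blocks translation. The deposited values are intensities on a linear scale, 1 per probe set and array. The mean after trimming 2% from each end was the same on all 12 arrays, as in global scaling of the MAS type; this was read from the values, and the software that made them is not given in the sources used here. Detection calls were not used here. Array columns matched the samples by name, and no pair of arrays shared over 1% of values.

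Intensities were floored at 16 and taken to log2, since the values were linear. The 64 Affymetrix control probe sets were left out, and 22746 were tested. Of all probe sets, 13513 had 1 gene in the platform annotation used here, 503 had several and 8730 none. Names were updated through Entrez IDs against the TAIR10.1 gene table, where 13436 matched. A gene without a symbol carries its locus name. ABI3 is not named in the annotation used here, so its own level is not reported. Where a gene had several probe sets, the one with the highest mean over the 12 arrays stood for it. A value at the floor has no order; a fold against a group wholly at the floor is given as "at least".

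Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on all 12 arrays, which share 1 estimate of the spread per probe set. The comparisons were DEX without CHX, DEX with CHX, CHX without DEX, their interaction and the DEX effect averaged over CHX. Adjusted p-values are Benjamini-Hochberg over the 22746 probe sets, with a threshold of 0.05. Group SDs are over 3 arrays and standard errors come from the fit. No arrays of protoplasts without the construct, or of an empty construct with DEX, were used here.

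Gene lists were tested with limma's camera at a preset correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists within a comparison; camera with an estimated correlation and fry were alternatives. The 18 first lists, with 294 entries, were written before the data were examined. The annotation named probe sets for only 46 entries: 5 lists had at least 4 measured genes and were tested, 11 had 1 to 3, and 2 (the jasmonate pathway and stele markers) had none. A further 20 lists were written after the annotation had been read and before any effect of a treatment was examined; those that widen a first list are called extended, and the others are gene families, organelle genes and ER genes. The matching of entries to loci was corrected after results had first been seen, to follow the rule as written. All 10 LEA and desiccation genes are also in the extended seed list, and the 5 ribosomal protein genes in the extended ribosomal list.

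Named genes follow a rule set before the data were examined: the 10 largest rises and 5 largest falls per main comparison among genes past the threshold whose arrays do not overlap, up to 5 each way for the interaction, up to 10 shared by both DEX comparisons, and up to 4 members of a list past the threshold (or 2 of highest mean if none passed). Exceptions are named as chosen after their values were seen. CHX in cells given DEX was compared after seeing the data.

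The fit was tested on simulated data for the DEX effect with CHX, on 22746 probe sets: of 100 probe sets changed 2-fold, 16 were recovered, and of 100 changed 4-fold, 61. Of the 22546 left unchanged, 6 were called. The changed probe sets were drawn from those with a mean more than 2 above the floor in log2, so dimmer ones were not tried. A list of 10 genes shifted 2-fold had a camera p of 4.04e-11, and 2 of 20 random lists had a p under 0.05. The simulated noise was independent between genes, so this does not test whether the preset correlation suits the real lists. When the real arrays without CHX were split otherwise, camera at that correlation called up to 7 lists, where the real groups gave 0. Its p-values can thus be too small here, and a call at the preset correlation is not by itself evidence of an effect.

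Alternatives were quantile normalization, centring on medians, a floor of 64, a pseudocount of 1 with no floor, leaving out the probe sets of lowest mean, no variance trend, an unmoderated fit, array weights, the replicate number as a block, only the 6 arrays compared, a 2-fold minimum, and each array left out in turn. Leaving out both arrays of lowest weight, and centring and the floor of 64 for the gene lists, were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.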

Results

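Protoplasts, cells freed of their walls, were made from Arabidopsis roots (ecotype Columbia) and transformed with a form of ABI3 held outside the nucleus until dexamethasone (DEX) lets it in. ABI3 is a transcription factor best known for switching on the genes of seed maturation. The cells received 10 µM DEX or none, and 35 µM cycloheximide (CHX), an inhibitor of protein synthesis, or none. The 4 combinations had 3 arrays each. The design asks which genes respond to nuclear ABI3 at all, and which of them respond while translation is blocked and so without newly made intermediate proteins. Every array had been scaled to the same trimmed mean, and the median intensity of the 12 arrays ran from 115.5 to 220.8. Between 2.84% and 17.9% of probe sets on an array lay at or under the floor of 16. Across probe sets, arrays of the same group correlated at 0.893 to 0.950, and arrays that differed in CHX at 0.759 to 0.834. Arrays that differed only in DEX correlated at 0.868 to 0.943, close to the range within groups. Hybridisation controls were nearly missing on replicate 1 of CHX alone, at a geometric mean of 230.7 against 8733 to 15996 on the other 11 arrays. The number of arrays limits the precision, and the labels do not say that replicates were separate preparations, so p-values measure only the spread between these samples. The median change of all probe sets was 0.10 for DEX without CHX, -0.12 for DEX with CHX, -0.05 for CHX alone and -0.22 for the interaction, and went to -0.10, 0.04, 0.08 and 0.14 with arrays centred on their medians. Values below are log2 intensities as deposited, and each fitted change rests on n = 3 arrays per group.

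DEX without CHX asks for direct and indirect responses together. AT2G47950 rose 9.28-fold, from 7.26 ± 0.14 (SD, n = 3) to 10.47, the largest rise of a named gene past the threshold (log2 change 3.21, SE 0.34; limma adjusted p = 0.00778). It was the only named gene past the threshold. The other probe sets past it, 257654_at (2.51-fold, limma adjusted p = 0.00778) and 245173_at (2.74-fold, limma adjusted p = 0.032), have no gene in the annotation used here. They were singled out after their values were seen. The seed maturation genes moved little: over the extended list of 42 genes the mean level was 10.05 ± 0.03 (SD, n = 3) without either treatment and 10.20 ± 0.13 (SD, n = 3) with DEX. The LEA and desiccation list, whose proteins protect drying cells, had a median log2 change of 0.17 (0.07 without replicate 1 and 0.26 without replicate 2 of DEX alone), with 6 of 10 members above 0. None of its members passed over all probe sets, and 2 were higher adjusted over the list alone. The oil body gene OLEO3 had a log2 change of 2.03 (SE 0.53) that missed the threshold (limma adjusted p = 0.549), and the storage protein gene PAP85 one of 0.27 (SE 0.66). OLEO3 was higher adjusted over the list alone, a list of 2 measured genes.

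In all, 3 of 22746 probe sets passed in limma, all higher, and 1461 had an unadjusted p under 0.05 where chance gives 1137. None of the 25 tested gene lists was called by limma's camera, with an estimated correlation or by fry, and 2, 1 and 2 had an unadjusted p under 0.05. The median standard error was 0.45, and changes of 4-fold can be missed. The estimate for OLEO3 did not pass, and whether that gene changed is not shown. The count fell to 0 without replicate 1 or 2 of the cells with neither treatment, without replicate 1 or 3 of DEX alone, or without the variance trend, to 1 without replicate 2 of DEX alone, and rose to 21 with a floor of 64. AT2G47950 lost its call without any of these 5 arrays, without the trend and in the unmoderated fit, and the LEA and desiccation list was called after quantile normalization but had a median under 0 after centring. Single settings also called the plastid-encoded list (quantile normalization; without replicate 1 of neither treatment) and the extended wound and ER quality control lists (without replicate 3 of DEX alone).

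DEX with CHX asks for responses that need no new protein. The 10 largest rises of named genes included LEA genes and a seed maturation protein gene. AT2G47950 rose 29.1-fold (log2 change 4.86, SE 0.34; limma adjusted p = 4.31e-05), from 6.90 ± 0.39 (SD, n = 3) with CHX alone to 11.77 ± 0.82 (SD, n = 3) with both. AT3G54940, which encodes a papain-type protease, rose 10.9-fold, and AT3G22490, a seed maturation protein gene, 6.95-fold. The LEA gene AT4G36600 rose 6.75-fold, LEA18 4.45-fold and the LEA gene AT3G53040 4.40-fold. The remaining named genes with the largest rises were AT5G45690 (6.02-fold), AT2G47960 (5.76-fold), AT1G54860 (5.47-fold) and AT1G54870 (4.64-fold). No named gene fell past the threshold. These rises are measured against cells with CHX alone. Over the 36 genes raised, the median level was 11.48 with neither treatment, 10.17 with CHX alone and 11.71 with both. As a set they thus stood near the untreated level with both treatments, while AT2G47950 stood above it (7.26 untreated and 11.77 with both).

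**Figure D1:**
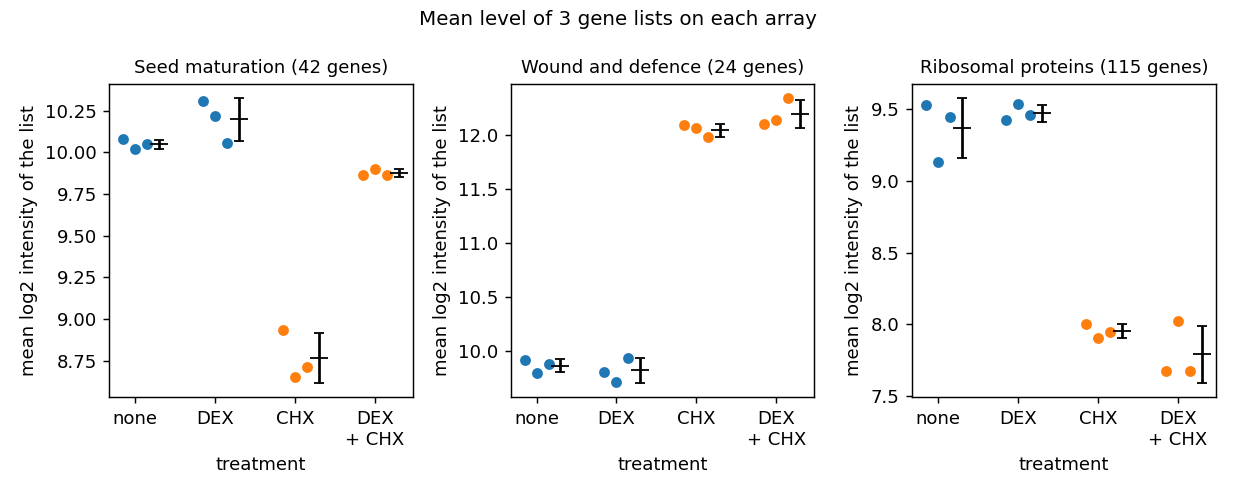
Mean log2 intensity of the genes of 3 lists on each of the 12 arrays (points, blue without CHX and orange with CHX), with the group mean and SD of 3 arrays as black bars; the vertical axes do not start at 0. The seed maturation list stood at 10.05 with neither treatment, 8.77 with CHX alone and 9.88 with both treatments. The wound and defence list rose and the ribosomal protein list fell with CHX.

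Of the 10 measured LEA and desiccation genes, 4 rose (LEA18, AT3G53040, AT4G21020 and LEA4-5), and all 10 were higher adjusted over the list alone. The median log2 change of the list was 1.29, and it was called by camera (limma adjusted p = 1.61e-25; adjusted p = 0.00867 with an estimated correlation). Of the 42 genes of the extended seed maturation list, 15 rose, none fell and 34 had changes above 0. Its median was 1.18 (limma adjusted p = 2.7e-44 by camera; adjusted p = 0.00051 with an estimated correlation). AT2G25890, an oleosin gene, and the cupin genes AT2G18540 and AT2G28490, relatives of storage proteins, were among those that rose, by 2.05, 2.06 and 1.73 on the log2 scale; they were picked from the list after their values were seen. The extended ABA and dehydration list held 4 of 19 genes that rose, among them AT3G02480 (log2 change 1.57, SE 0.25) and the ubiquitin ligase gene PUB19 (1.15, SE 0.20). Its median was 0.12 and it was called (limma adjusted p = 2.68e-07 by camera; adjusted p = 0.00836 with an estimated correlation), though the median ran from 0.02 without replicate 1 of both treatments to 0.34 without replicate 2. In the other direction, none of the 7 ER body genes passed alone, and all 7 had changes under 0, with NAI2 at -0.79 and JAL34 at -0.17; 2 were lower adjusted over the list alone. ER bodies are stores of beta-glucosidase found in seedlings and roots. The list median was -0.82 (limma adjusted p = 0.00122 by camera; adjusted p = 0.0338 with an estimated correlation). The extended wound and defence list, with PUB19 its one member that rose, was called higher at a median of 0.16 (0.06 without replicate 3 of both treatments), a call lost with an estimated correlation (adjusted p = 0.109). The same held for 4 rapid stress regulators (median 0.39; adjusted p = 0.109 with an estimated correlation) and for the extended auxin list (median 0.19, and 0.11 without replicate 1 of both; adjusted p = 0.0835 with an estimated correlation). These 3 calls were also lost after quantile normalization. Of the rapid stress regulators 1 was higher adjusted over the list alone. Storage protein and oil body genes of the first list had 2 measured members, PAP85 (0.12, SE 0.66) and OLEO3 (-0.04, SE 0.53), neither past the threshold.

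In all, 62 probe sets passed in limma, 58 higher and 4 lower, of which 36 had 1 gene, all higher. The fit of only the 6 arrays compared called 0 probe sets, with 1608 at an unadjusted p under 0.05, and limma without the variance trend called 28. The count was 21 without replicate 2 and 28 without replicate 3 of CHX alone, 30 without replicate 1 or replicate 3 of both treatments, and 112 without replicate 2 of both. Of those 112, 69 were higher and 43 lower, so the small number of falls depends on that array. AT4G21020, LEA4-5 and PUB19 each lost the call in 13 of 23 alternatives, AT3G02480 in 9, AT2G47960 in 8 and AT3G22490 in 7. Without the 2 arrays of lowest weight, an alternative added after seeing the data, 393 passed, 107 higher and 286 lower, and all 62 were among them. The ubiquitin 3' to 5' ratio, a mark of RNA integrity and labelling, was 3.92, 3.95 and 3.89 on the arrays with CHX alone and 7.78, 4.86 and 8.59 on those with both, so RNA quality was not separated from DEX here; the GAPDH and actin ratios of these groups overlapped.

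The DEX effect with CHX was next set against that without it. All 3 probe sets that passed without CHX also passed with it, higher in both, where independent lists would share 0.00765. Both comparisons use the same estimate of the spread per probe set, so their lists are not fully independent. The overlap was 0 without replicate 1 or 2 of neither treatment or replicate 1 or 3 of DEX alone, and 1 without replicate 2 of DEX alone. AT2G47950 was the only named gene among them. Its rise was larger with CHX by 1.65 on the log2 scale (SE 0.48), a difference that missed the threshold (limma adjusted p = 0.397). Of the 58 probe sets higher with CHX, 39 had changes above 0 without it (67.2%, against 59.4% of all probe sets), with a median of 0.22 against 1.66. Across all probe sets, which are not independent replicates, the effects correlated at -0.156. The test of the difference itself, the interaction, called 1 probe set, 260716_at, which has no gene in the annotation used here. It was at 13.21 ± 0.16 (SD, n = 3) without either treatment, 13.98 with DEX, 7.15 with CHX and 10.67 with both (interaction 2.75, SE 0.30; limma adjusted p = 0.015). As a group, seed maturation genes differed: the extended list had a median interaction of 1.20, with 33 of 42 members above 0 (limma adjusted p = 2.83e-28 by camera; adjusted p = 0.00262 with an estimated correlation). The LEA and desiccation list had 1.17, with 10 of 10 above 0 (limma adjusted p = 1.19e-14; adjusted p = 0.0458 with an estimated correlation), and 7 of 10 adjusted over the list alone. The extended ABA and dehydration list was called at a median of 0.05 (limma adjusted p = 0.000662; adjusted p = 0.0458 with an estimated correlation), which went to -0.09 without replicate 2 of DEX alone and 0.35 without replicate 2 of both. The rapid stress regulators (0.35) and the extended wound and defence list (0.32) lost their calls with an estimated correlation (adjusted p = 0.302 and 0.131), and these 2 lists and the ABA list lost them after quantile normalization and with fry. On all 12 arrays only fry called the ER body genes (median -1.08, -0.66 without replicate 3 of both and -0.28 with a floor of 64; adjusted p = 0.0162) and the UDP-glycosyltransferases (-0.35, -0.58 without replicate 2 of both and 0.01 with centring; adjusted p = 0.034), both lower. Without replicate 3 of both, camera called the ER body genes too. The count of 1 fell to 0 with a floor of 64, without the trend, in the unmoderated fit, with the replicate number as a block, without replicate 1, 2 or 3 of neither treatment, without replicate 1 or 2 of DEX alone, or without replicate 1 of both. It was 15 without replicate 1 of CHX alone, 3 without replicate 3 of both and 2 without replicate 3 of DEX alone.

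**Figure D2:**
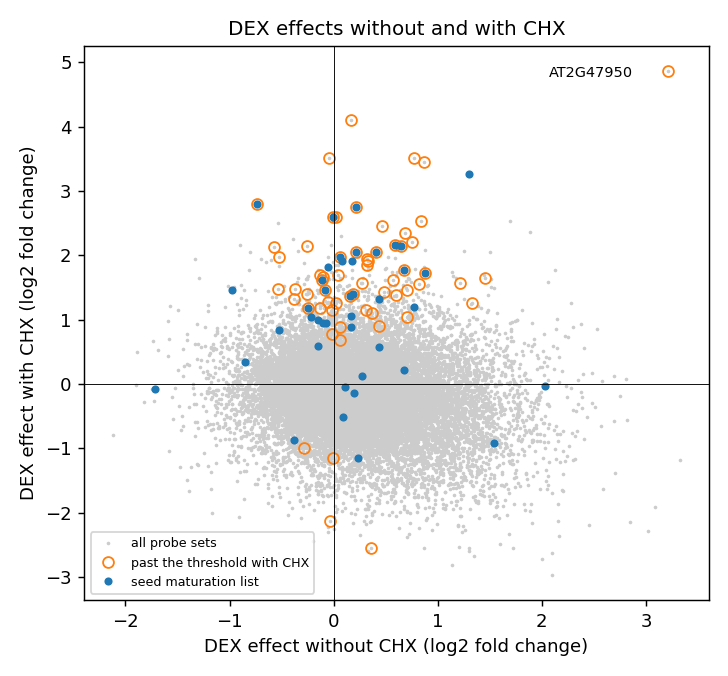
Log2 fold change with DEX in cells without CHX (horizontal) and with CHX (vertical) for all 22746 probe sets (grey), with the 62 past the threshold with CHX circled and the 42 genes of the extended seed maturation list in blue. AT2G47950 lies far from 0 on both axes (3.21 and 4.86), while the 58 probe sets higher with CHX have medians of 0.22 on the horizontal and 1.66 on the vertical axis.

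Averaged over CHX, DEX raised 29 probe sets and lowered none in limma (1443 had an unadjusted p under 0.05). AT2G47950 led the named genes at 16.4-fold (log2 change 4.04, SE 0.24; limma adjusted p = 1.25e-05). This average includes the DEX effect with CHX, so it is not separate evidence. The mean effect on the 42 seed maturation genes was 1.11 with CHX and 0.151 without. Averaged, 8 of 42 genes of the extended list were higher (median 0.65; limma adjusted p = 3.28e-29 by camera; adjusted p = 0.00233 with an estimated correlation). So were 3 of 10 LEA and desiccation genes, 8 of 10 adjusted over the list alone (median 0.74; limma adjusted p = 1.05e-18; adjusted p = 0.0226 with an estimated correlation). The extended ABA list (median 0.11, and 0.29 without replicate 3 of both; adjusted p = 0.0154 with an estimated correlation) and the ER body list (median -0.28, and -0.63 without replicate 2 of both; adjusted p = 0.0262 with an estimated correlation) were the other lists called. The count was 50 after quantile normalization, 19 with centring, 10 unmoderated and 8 without the variance trend. Without 1 array it was 11 (replicate 3 of neither treatment, 3 of CHX alone or 1 of both), 15 (replicate 1 or 3 of DEX alone or 2 of CHX alone) or 17 (replicate 1 of neither or 3 of both).

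CHX alone changed far more of the transcriptome than DEX did. The largest rise of a named gene was that of AT2G43590, a chitinase family gene, which was at the floor on all 3 arrays without treatment and rose at least 128-fold (limma adjusted p = 5.86e-06). The beta-glucosidase gene BGLU31 rose 121-fold, the lectin family gene AT5G03350 110-fold and AT1G22810, an ERF family transcription factor gene, 102-fold; each was at the floor on 1 of the 3 arrays without treatment, so these folds depend on the floor. AT1G14730, AT5G07870, AT2G17660, AT2G37810, AT5G28630 and AT5G07860 rose between 68.6-fold and 92.6-fold. Among genes named in the annotation used here, the deepest falls were those of AT3G14280 (57.4-fold, with 1 array with CHX at the floor), AT2G03200 (46.4-fold, with 2 arrays with CHX at the floor), AT2G30840 (37.3-fold), HCT (34.0-fold), an enzyme of lignin synthesis, and AT1G62660 (32.6-fold), an invertase family gene. The folds of AT3G14280 and AT2G03200, and so their order, depend on the floor.

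Defence and wound genes rose together. Of 24 genes on the extended wound and defence list, 20 rose and 1 fell, with a median log2 change of 2.17 (limma adjusted p = 2.2e-17 by camera; adjusted p = 0.00604 with an estimated correlation). ORA47 (5.79, SE 0.31), a jasmonate-linked transcription factor gene, WRKY53 (5.35, SE 0.25), AT3G02840 (4.07, SE 0.23) and the calmodulin-like gene CML23 (3.47, SE 0.25) led it. All 4 measured genes of the list of rapid stress regulators rose, also adjusted over the list alone: WRKY53, STZ (3.07), WRKY6 (1.38) and WRKY22 (0.52), the last not past the threshold in 6 of 23 alternatives. That list was called (limma adjusted p = 2.2e-05; adjusted p = 0.0283 with an estimated correlation). Of 4 early auxin response genes, GH3.1 (3.64) and GH3.3 (2.93) rose and WES1 (-1.26) fell, the same numbers adjusted over the list alone, and the list missed the call by camera (limma adjusted p = 0.072) but was called by fry.

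Genes of the ribosome itself and of its assembly moved in opposite directions. Of 115 cytosolic ribosomal protein genes on the extended list, 82 fell and 1 rose, with a median of -1.64 (limma adjusted p = 1.64e-23 by camera; adjusted p = 0.00604 with an estimated correlation). AT1G74270 (-4.23, SE 0.77) and AT3G11510 (-3.99, SE 0.63) fell furthest, and all 5 measured genes of the first list fell, also adjusted over the list alone (median -2.13; limma adjusted p = 9.88e-07; adjusted p = 0.0136 with an estimated correlation). Of 31 ribosome biogenesis genes on the extended list, 13 rose and 1 fell (median 0.67; limma adjusted p = 0.000337; adjusted p = 0.0172 with an estimated correlation), with AT5G38720 at 1.81 (SE 0.26). Of the first list, 3 of 6 rose, also adjusted over the list alone (median 0.94; limma adjusted p = 0.00163; adjusted p = 0.0279 with an estimated correlation).

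Seed maturation, ABA and ER body genes were lower with CHX. Of the 36 genes raised by DEX with CHX, 26 fell with CHX alone and 4 rose, but the 3 arrays of CHX alone enter both comparisons with opposite signs. In the extended seed maturation list 22 of 42 fell and none rose (median -1.40; limma adjusted p = 1.17e-08; adjusted p = 0.0225 with an estimated correlation), led by the cupin gene AT2G28490 (-3.86, SE 0.25) and AT4G36600 (-3.53, SE 0.30). LEA18 fell from 13.75 ± 0.18 (SD, n = 3) to 10.61 ± 0.46 (SD, n = 3). The LEA and desiccation list had 7 of 10 genes lower, 9 adjusted over the list alone with 1 higher, at a median of -1.47, a call lost with an estimated correlation (adjusted p = 0.186). In the extended ABA list 11 of 19 fell and 1 rose (median -1.15; limma adjusted p = 2.98e-05; adjusted p = 0.0151 with an estimated correlation), with OSM34 at -4.33 (SE 0.19) and HIS1-3 at -3.31 (SE 0.27). ER body genes fell in 4 of 7 cases, among them JAL33 (-4.91, SE 0.48) and PYK10 (-4.75, SE 0.18), the main ER body beta-glucosidase gene (list median -1.41; limma adjusted p = 0.0022; adjusted p = 0.0282 with an estimated correlation).

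**Figure D3:**
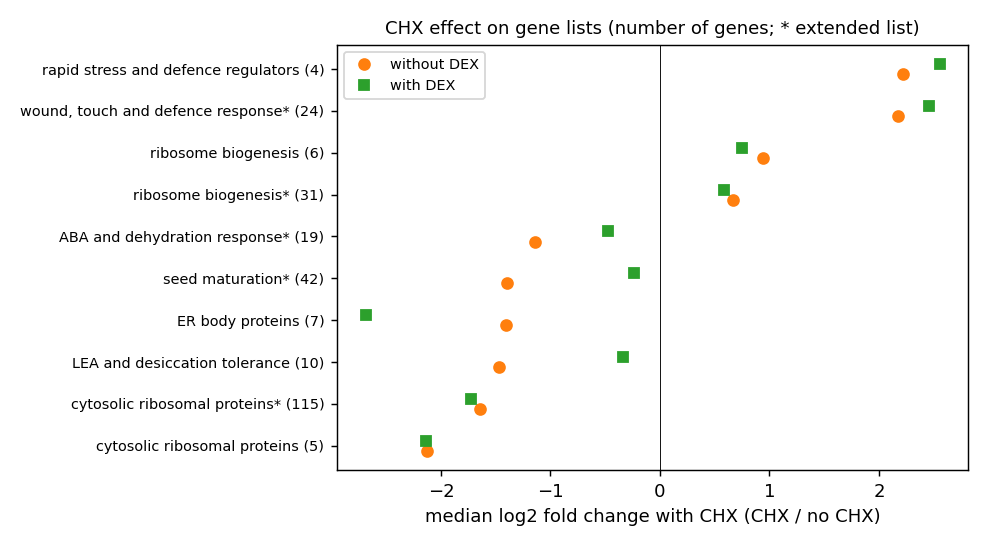
Median log2 fold change with CHX over the genes of each list called by camera, in cells without DEX (circles) and with DEX (squares); numbers of genes are in parentheses and a star marks an extended list. The seed maturation list lies at -1.40 without DEX and -0.24 with DEX, and the extended ribosomal protein list at -1.64 and -1.73.

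In all, 6126 of 22746 probe sets passed in limma, 2473 higher and 3653 lower, and 5069 of them changed at least 2-fold. Higher calls made up 40.4% as deposited and 48.0% with arrays centred on their medians. The GAPDH 3' to 5' ratio was 1.61 ± 0.31 (SD, n = 6) without CHX and 1.20 ± 0.14 (SD, n = 6) with it, that of actin 1.98 ± 0.41 and 2.08 ± 0.52, and that of ubiquitin 5.37 ± 0.47 and 5.50 ± 2.13. In the groups compared here the ubiquitin ratio was 6.22, 5.27 and 5.35 with neither treatment and 3.92, 3.95 and 3.89 with CHX alone, so RNA quality was not separated from CHX.

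CHX in cells given DEX was compared as well, on the 6 arrays that the comparison of CHX alone does not use; this comparison was added after seeing the data. ORA47 (5.12, SE 0.31), WRKY53 (5.69, SE 0.25) and CML23 (3.38, SE 0.25) rose here too. The median change of all probe sets was -0.46, and 0.03 with arrays centred. In limma 7045 probe sets passed, 2411 higher and 4634 lower. Both CHX comparisons called 4988, of which 4974 went the same way, where independent lists would share 262.1 higher and 744.2 lower. The estimate of the spread per probe set is common to both, so these lists are not fully independent either. The extended seed maturation list was not called here, at a median of -0.24 (limma adjusted p = 0.846 by camera), with 7 genes higher and 9 lower. The LEA and desiccation list was not called either (median -0.34; limma adjusted p = 0.846).

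Markers of other cell types, fixed beforehand, had few measured members. The endodermis and cortex gene AT1G62500 had log2 changes of 2.21 (SE 0.64) with DEX without CHX, -1.39 with DEX with CHX and 1.501 with CHX alone, none past the threshold. It was at the floor on 2 of 3 arrays with neither treatment and on 2 of 3 with both, so these changes, and its passes as the only measured gene of its list, rest on the floor. The root hair genes EXPA7 (-1.06, SE 0.68) and EXPA18 (0.26, SE 0.76), the root cap gene CR4 (0.09, SE 0.79) and PRL (-0.62, SE 0.73), of dividing cells, did not pass with CHX alone, and none of the 4 passed with DEX. Of 2 green tissue genes, RCA fell with CHX (-1.18, SE 0.32; limma adjusted p = 0.0128), also adjusted over the list alone, and LHCB4.1 had 0.27 (SE 0.23). The reference genes AT2G28390 (-1.77, SE 0.54) and AT4G34270 (-0.93, SE 0.25), often used to normalise qPCR, also fell with CHX (limma adjusted p = 0.026 and 0.0143), both also adjusted over the list alone. AT2G28390 no longer passed in 6 of 23 alternatives, AT4G34270 in 4, quantile normalization and centring among them, and RCA in 2.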

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

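The tests of unequal spread, of the signal range and of the fall with CHX were chosen after the result was seen, and that of the array with most values at the floor before.

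The interaction picked out 1 probe set and, at the preset correlation, 5 gene lists, of which 3 stayed called with an estimated correlation; the rapid stress and wound lists did not (adjusted p = 0.302 and 0.131). By fry only the seed and LEA lists of these 5 were called, with the ER body genes and UDP-glycosyltransferases beside them. Probe set 260716_at, without a gene in the annotation used here, had a DEX effect larger by 2.75 on the log2 scale with CHX. Median differences were 1.17 for the LEA and desiccation list, 1.20 for the extended seed maturation list, 0.35 for the rapid stress regulators, 0.05 (0.0501) for the extended ABA list and 0.317 for the extended wound and defence list. Groups of 3 arrays were too small to test single arrays as outliers. Array weights ranked them, lowest for replicate 2 of neither treatment (0.438) and replicate 2 of both (0.468), against 0.825 to 1.67 on the others.

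The larger DEX effect on seed maturation genes with CHX was weighed as a pattern: the mean effect on the 42 genes was 1.11 with CHX (95% interval 0.872 to 1.35) and 0.151 without (-0.0592 to 0.361). These 2 intervals take 4 degrees of freedom although the group SDs differed (0.149 with CHX alone, 0.0219 with both), so they are too narrow. Unequal spread between arrays is argued against, since the interval of the difference, with each pair of groups keeping its own spread, starts at 0.642; leaving out the array with the most values at the floor moved that bound to 0.61. A ceiling on bright signals is argued against as the whole cause, since the bound was 0.18 for the 23 genes below the 90th percentile. A candidate explanation is that the genes that responded were already raised without DEX, with CHX lowering that level and leaving room for a rise. Genes chosen for their rise without 1 array of CHX alone had median changes of -1.20, -2.02 and -1.96 on the left-out array. Genes matched on level had 0.259, 0.0974 and 0.111. A raised level was not itself measured, since no cells without the construct were used here. Nor were cells with an empty construct given DEX, so a response to DEX itself was not separated from one to ABI3. Leakage of the fusion protein, the cells' own ABA response, protoplasting, RNA quality and an action of CHX on feedback regulators stay open.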

How the results depend on the processing

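The count for CHX without DEX stayed within 1.5 times of 6126 in every alternative (5105 to 6380 when each array was left out), and the count of called lists, 26 over 5 comparisons, ran from 26 to 30 in the same way and from 20 (estimated correlation) to 33 (2 arrays of lowest weight left out) overall. Of 118 named gene results past the threshold, 83 kept direction and call under all of up to 23 alternatives, all of them with CHX; none of the 14 for DEX with CHX did, 8 of these because of the fit of 6 arrays alone. For DEX without CHX the main count of 3 became 5 with quantile normalization and in the unmoderated model, 1 with median centring, 21 with a floor of 64, 0 without the variance trend (1334 at an unadjusted p under 0.05), 1 with only the 6 arrays compared and 0 to 3 with each array left out. For DEX with CHX 62 became 28 without the trend, 30 unmoderated, 0 with only the 6 arrays compared, and 21 to 112 with each array left out. For the interaction 1 became 12 with quantile normalization, 7 with median centring, 5 with a pseudocount of 1, 15 without the probe sets of lowest mean, 0 with a floor of 64, without the trend or unmoderated (1746 at an unadjusted p under 0.05 without the trend), and 0 to 15 with each array left out. For the averaged DEX effect 29 became 50 with quantile normalization, 19 with median centring, 8 without the trend, 10 unmoderated and 11 to 30 with each array left out. The overlap of 3 was 0 to 3 with each array left out. The fits without some arrays hold fewer samples; the cause was not tested for the others. Leaving out both arrays of lowest weight, chosen after seeing the data, gave 1 for DEX without CHX, 393 for DEX with CHX, 0 for the interaction and 1 for the overlap, and turned the plastid-encoded list to a called median of -0.375 for DEX with CHX and -0.237 averaged. The SWEET2 rise with CHX (0.56) went to -0.01225 with quantile normalization. With the replicate number as a block, the counts were 2, 45, 5786, 0 and 20 in the order without CHX, with CHX, CHX alone, interaction and averaged, and the overlap 2. Same-numbered arrays did not deviate together: 4 of 18 pairs correlated over 0.1 (range -0.439 to 0.294), as did 13 of 36 with other numbers, and 2 of 12 arrays correlated best with their own number. Dim signals limit what can be seen, with up to 17.9% of probe sets at the floor on an array.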

Other observations

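The tests of array scaling, of the other 6 arrays, of neighbouring genes and of the seed and LEA lists in other splits were chosen after the result was seen; the others were set down before.

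Some of the other lists held both rises and falls with CHX alone. Among 14 SWEET sugar transporter genes 4 rose and none fell, with SWEET8 at 5.63 (SE 0.42) and SWEET16 at 3.23 (SE 0.29). Among 27 expansin and XTH genes, which loosen and remodel cell walls, 5 rose and 3 fell, from EXLA3 at 4.101 (SE 0.16) to EXPA4 at -3.62 (SE 0.23). Of 15 tetraspanin genes TET9 was at 4.88 (SE 0.43) and TET6 at -3.82 (SE 0.52). TET3 and TET4 also passed, but not in 4 and 2 of 23 alternatives. In the ER protein quality control list BZIP60, a regulator of the unfolded protein response, rose (1.77, SE 0.18), while ATERDJ3B (-2.50, SE 0.39) and CRT1b (-1.95, SE 0.32) fell. Of 69 plastid-encoded genes 3 fell and none rose, with a median of -0.15 (-0.54 without replicate 2 and 0.06 without replicate 1 of neither treatment), and of 14 mitochondrion-encoded genes 1 rose. By camera, none of these lists was called as a whole (limma adjusted p by camera 0.175, 0.22, 0.821, 0.332, 0.442 and 0.588 in this order), although fry called the SWEET and ER quality control lists, and camera called the plastid-encoded list without replicate 2 of neither treatment. On the extended auxin list 5 of 16 rose and 4 fell, with IAA30 at 4.42 (SE 0.35) and GH3.17 at -2.59 (SE 0.27), and it was not called by camera (limma adjusted p = 0.397) but was by fry.

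By camera, the remaining lists were not called with CHX alone either (limma adjusted p from 0.106 to 0.925): heat shock proteins (4 of 15 rose), UDP-glycosyltransferases (8 rose, 8 fell of 47), glutathione S-transferases (2 and 2 of 13), subtilases and carboxypeptidase-like genes (3 and 5 of 36), AGAMOUS-like factors (5 of 40 fell), CYP71B genes (4 and 2 of 18) and nuclear photosynthesis genes (3 of 11 fell). By fry, the CYP71B and photosynthesis lists were called. The seed regulator EEL had 0.24 (SE 0.25) and the seed gene AGL67 -1.31 (SE 0.47). The ABA response genes COR47 (-0.23, SE 0.21) and COR15A (1.80, SE 0.65), the fatty acid gene FaTA (-1.48, SE 0.82) and the heat shock gene AT1G53540 (0.40, SE 0.33) completed the first lists with PAP85 (-1.83, SE 0.66), and none of these 7 genes passed the threshold. Adjusted over the list alone, PAP85 and AGL67 were lower and COR15A higher.

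The fall of ribosomal protein genes with CHX was weighed as a second pattern. Scaling is argued against, since the list median was -1.49 after quantile normalization and -1.51 after centring, although centring, which kept the preset-correlation call, ended that with an estimated correlation (adjusted p = 0.112 against 0.00604 as deposited) for a cause not tested. The array without hybridisation controls is argued against, with a median of -1.68 without it. Chance differences of these arrays are argued against by a median of -1.73 on the 6 arrays given DEX. That holds only if replicates were separate preparations, which the labels do not say. A response to blocked translation, changed RNA stability and RNA quality remain open.

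Genes raised by DEX with CHX held 2 pairs of neighbours, AT2G47950 with AT2G47960 and AT1G54860 with AT1G54870. Random lists of 36 measured genes held 0.0475 pairs on average, and 13 of 10000 held as many (permutation p = 0.0014). These pairs prompted the test, so it leaves chance placement along the chromosomes open. Promoter sequence was not analysed here.

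Other splits of the arrays were fitted the same way. With 6 arrays only 10 splits exist, too few for a share under 0.05: the real split gave 3 probe sets for DEX without CHX (highest other 0), 62 for DEX with CHX (highest other 1) and 6126 for CHX (highest other 0), each the highest 1 of 10. Called lists were 0 for DEX without CHX, matched by all 10 splits (highest other 7), 7 for DEX with CHX, reached by 2 splits (highest other 8), and 10 for CHX (highest other 7). The camera p of the seed and LEA lists for DEX with CHX, 1.08e-45 and 1.29e-26, were each reached in 1 of 10 splits, and the smallest others were 3.5e-12 and 1.1e-11. Over 100 drawn regroupings of DEX within CHX, the averaged effect called 29 probe sets (highest other 9), reached by 1 of 100, the real one. That is the smallest share that 100 draws can give. It argues against chance only if replicates were separate preparations, which the labels do not say. The overlap held 3 (highest other 0), also in 1 of 100, but other splits of the arrays without CHX called no probe set to share, so this does not decide about chance. Chance is not excluded for the interaction count of 1, reached by 12 of 100 (highest other 9), nor for the 4 lists called for the averaged effect, reached by 37 (highest other 9), or the 5 of the interaction, reached by 27 (highest other 8). Each regrouping with more than 1 interaction probe set kept the real groups with CHX, and so the DEX effect there. The seed list had as small a p as the real 1.31e-30 in 7 regroupings averaged (smallest other 9.1e-39) and as the real 1.13e-29 in 8 for the interaction (1.9e-41). The LEA list had as small a p as 8.38e-20 in 5 averaged (1.2e-22) and as 9.52e-16 in 9 for the interaction (9.4e-22). All of these regroupings keep the real groups with CHX, as 12 of the 100 do, and with them the rise of these genes, so the 4 counts do not decide about chance.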
